A study of Mus musculus with 57 samples.

How the data were processed

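RNA was sequenced from the prefrontal cortex of 57 C57BL/6N mice taken on postnatal day 25. The mice were heterozygous for Shank2 (HT) or wild type (WT), of both sexes, and had received fluoxetine, lithium or vehicle through the milk of the mother from postnatal day 3 to 24. Libraries were made with a stranded poly(A) mRNA kit, per the labels' protocols. The 12 groups of genotype, drug and sex held 5 libraries each, except WT lithium females, WT vehicle females and WT vehicle males, which held 4.

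The deposited values are a signal per gene and library that is never negative, namely normalized estimated counts. Per the submitters' processing notes, Salmon 0.11.2, R 3.6.0 and DESeq2 1.19.11 were used, with the mouse genome GRCm38. The annotation release, the filters and the strand setting of the counting are not given in the sources used here. The deposited values are not whole, their totals are nearly equal in all libraries, and single reads do not have 1 common worth per library. They therefore carry a factor that differs between genes as well as between libraries, and whole reads could not be had from them. The table held normalized values, so limma replaced the test of counts that had been planned.

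The totals of normalized values ran from 30.4 to 33.2 M per library (M, mega). The commonest of the lowest values, held by few genes, was 0.861 to 1.34. Taken as the worth of 1 read for every gene, which these values do not have, it would imply 24.0 to 37.1 M reads per library with a median of 32.9 M, a rough estimate only. A gene near the minimum mean of 10 therefore rests on few reads, and its change is less certain than that of an abundant gene. Between 21509 and 23264 genes lay above zero in a library. Of 51456 identifiers in the table, 51285 had a gene symbol and 171 did not; 17 symbols belonged to several tested genes. Each column was matched to a sample by the library name in its description, and no column was left over. No pair of libraries held identical values. The SD of the log2 difference between libraries of a group was 0.372 to 0.696. Gene coordinates are those of GENCODE vM21 on GRCm38, counted from 1.

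Differences were tested with limma 3.58.1 in R 4.3.3, with trend and robust moderation, on log2(value + 1). A pseudocount of 1 understates the change of low genes. Genes with a mean of at least 10 over all libraries were tested, 16659 in all. All 57 libraries entered 1 fit of the 12 groups, so that the groups share an estimate of the spread of each gene. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Each effect over both sexes is the mean of the female and the male effect. The comparisons are HT against WT in vehicle libraries, each drug against vehicle in HT and in WT, the same within each sex, the differences of these effects between the sexes, and the difference of each drug effect between the genotypes. In the text, ± after a log2 change is the standard error of the fit, and ± after a mean is the SD over libraries. The labels give no litter. Drug reached the pups through the mother, so pups of 1 litter may share more than a drug, and p-values measure only the spread between these samples.

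Gene lists, 36 in number, covered cell types, neighbouring tissues, synaptic and metabolic pathways and signalling targets. They were tested in the 5 effects over both sexes with camera on the moderated statistics, at a preset correlation of 0.01, with adjustment over lists and effects. Camera with an estimated correlation, and fry, were run beside it. Fry tests whether the genes of a list move, on balance, in 1 direction and does not compare the list with other genes. The lists, the groups, the tests, the named-gene rule and most other settings tried were fixed before the data were examined. The correlation of effects across genes was computed with shared vehicle libraries split in 2 parts at random, 100 times, beside 100 simulated data sets without effects.

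The genes named are Shank2, Shank1, Shank3, Xist and Ddx3y; the 10 largest rises and 10 largest falls by log2 change among the called genes of each effect over both sexes; up to 4 members of each list that camera called, by smallest p; and, for effects within a sex and differences of effects, the 5 rises and 5 falls with the smallest adjusted p, predicted genes left out where others sufficed. Exceptions, chosen after their values were seen, are the genes next to Shank2, the genes called in both genotypes, and the genes of 3 comparisons added later (genotype over all treatments, and each drug over both genotypes), which follow the same rule of 10 rises, 10 falls and up to 4 members of a list. Some genes that these rules select are left out of the text.

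The tests were run first on simulated data: the residuals of the real libraries were shuffled within sex and 200 genes were changed by known amounts. Each comparison had 1 run. Residuals about group means spread less than the data, and shuffling takes outlying libraries out of their group. The shares found may therefore be too high. Of the genes changed by 0.25, 0.5 and 1 on the log2 scale, the fit found 43.3, 70.1 and 100% for genotype over both sexes. For fluoxetine in HT it found 47.8, 82.1 and 93.9%, for lithium in HT 61.2, 79.1 and 98.5%, for fluoxetine in WT 44.8, 71.6 and 97.0%, and for lithium in WT 44.8, 80.6 and 97.0%. For the sex difference in the fluoxetine effect in WT the shares were 7.5, 46.3 and 74.2%. Unchanged genes called numbered 8, 3, 1, 2 and 1 in the 5 effects over both sexes, 20 in the sex difference just named, 19 for genotype in males and 113 for fluoxetine over both genotypes. In a simulation of lithium in HT without any change in a list, camera with the preset correlation called 13 lists other than the ribosomal one, and camera with an estimated correlation and fry called 0.

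Other settings fixed in advance were pseudocounts of 0.5 and 10, no filter or a minimum mean of 50, scaling by trimmed means of ratios, the replicate number as a block, 2 surrogate variables, a fit of only the groups compared, and leaving out each library in turn. Chosen after the data had been seen were a fit without the 3 libraries of lowest median correlation with the rest, a fit with the mean log2 values of the olfactory bulb and striatal lists as terms (called dissection terms), both together, and a fit with the trend of each library with transcript length as a term (called the length term). Trimmed-mean scaling (30% of ratios, 5% of levels) and surrogate variables were written out in R, since the planned tools need counts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.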

Results

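Gene expression was measured by RNA sequencing in the prefrontal cortex of 30 HT and 27 WT mice. The mice were 25 days old and had received fluoxetine, a serotonin reuptake inhibitor, lithium, a mood stabilizer, or vehicle through maternal milk from day 3 to 24. Values are normalized estimated counts. As a rough estimate, since a read has no common worth in these values, the libraries held 24.0 to 37.1 M reads (M, mega). The median correlation of a library with the others was 0.968 to 0.986, with a median of 0.985. The lowest value belonged to WT vehicle male 2. The first 2 principal components carried 9.81 and 8.69% of the variance.

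Shank2, which encodes a scaffold protein of excitatory synapses (ENSMUSG00000037541, chromosome 7, 144001928 to 144424494), was lower in HT in every treatment and in both sexes. Its normalized count was 4388 ± 322 in HT (n = 30) and 9882 ± 1086 in WT (n = 27). The HT libraries ran from 3877 to 5006. The WT libraries other than WT vehicle male 2 ran from 8171 to 11791, and WT vehicle male 2 had 6762, so no HT library reached any WT library. In HT the group means were 4306 ± 275 in vehicle females, 4470 ± 318 in vehicle males, 4210 ± 346 in fluoxetine females, 4367 ± 277 in fluoxetine males, 4640 ± 284 in lithium females and 4332 ± 394 in lithium males. In WT they were 9831 ± 1454 in vehicle females, 9327 ± 1760.1 in vehicle males, 9221 ± 769 in fluoxetine females, 9955 ± 517 in fluoxetine males, 10440 ± 735 in lithium females and 10507 ± 912 in lithium males. In vehicle libraries the log2 change from WT to HT was -1.11 ± 0.06 (adjusted p = 3.69e-19), and neither drug changed Shank2 by a called amount in either genotype. The related scaffold genes did not pass in the same comparison: Shank1 had a log2 difference of 0.18 ± 0.09 (adjusted p = 0.309) and Shank3 of 0.03 ± 0.06 (adjusted p = 0.885). Xist, transcribed from the inactive X chromosome, had group means of 22550 to 27791 in females and 2.87 to 5.64 in males. Ddx3y, on the Y chromosome, had group means of 1229 to 1540 in males and 0 to 0.298 in females.

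**Figure D1:**
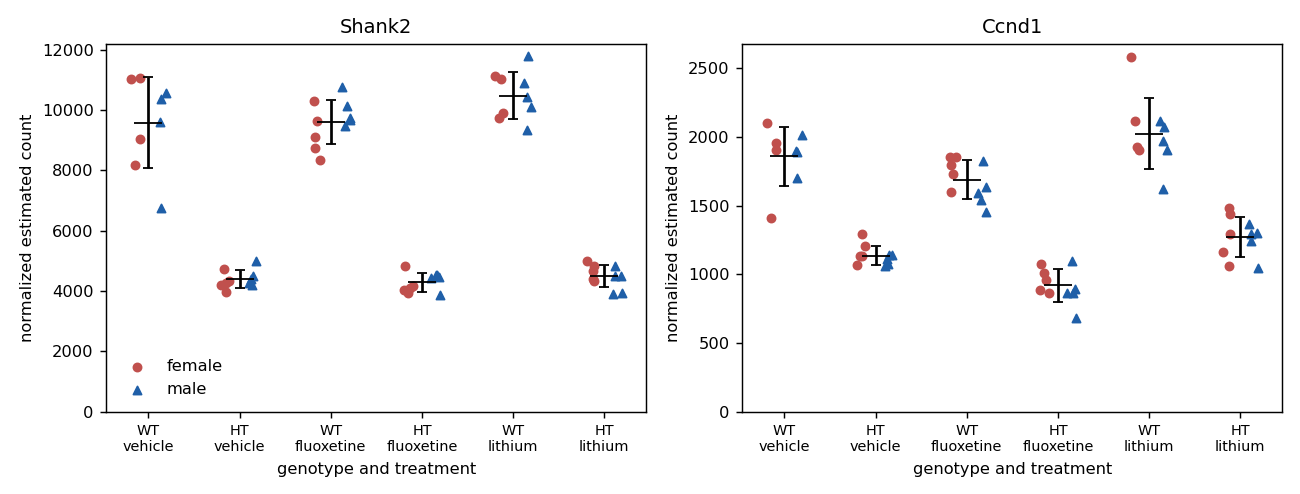
Normalized counts of Shank2 and Ccnd1 in each of the 57 libraries, by genotype, treatment and sex, with the mean and SD of each group. Shank2 was 3877 to 5006 in the 30 HT libraries and at least 6762 in the 27 WT libraries, and Ccnd1 was lower in HT than in WT on average.

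Comparing HT with WT under vehicle asks how cortical expression differs when Shank2 is heterozygous. Besides Shank2, the clearest changes were in genes of its own chromosomal region and in Hrk, Esr1 and Chrnb3. Ccnd1, which encodes cyclin D1 (chromosome 7, 144929931 to 144939925), fell from 1860.0 ± 216 in WT (n = 8) to 1136 ± 71.0 in HT (n = 10), a log2 change of -0.70 ± 0.07 (adjusted p = 2.64e-09). Hrk, a pro-apoptotic member of the BCL2 family, rose from 2479 ± 271 to 3445 ± 236 (log2 change 0.48 ± 0.07, adjusted p = 2.62e-05). Esr1, the estrogen receptor alpha gene, rose from 168 ± 20 to 263 ± 38.2 (log2 change 0.64 ± 0.11, adjusted p = 0.00231), and Chrnb3, a nicotinic receptor subunit, fell by 1.03 on the log2 scale (adjusted p = 0.0109).

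In all, 127 of 16659 genes were called, 88 higher and 39 lower in HT, and 2461 genes had an unadjusted p under 0.05. The called genes changed by a median of 0.253 on the log2 scale. Among the larger rises were Grp, a neuropeptide gene (0.51 ± 0.11, adjusted p = 0.0203), Lrrc27 (0.64), Tll2 (0.62), the protocadherin Pcdha1 (0.49) and the channel gene Trpc5 (0.48). Lrrc27 lies on chromosome 7, 4758.9 kb from Shank2. Gm49450 (1.14, adjusted p = 0.0435) is a predicted gene whose reads may be shared with other genes, and its change is uncertain. Among the larger falls were Clic6 (-1.87, adjusted p = 0.028), Ltbp2 (-1.54), the growth factor gene Nrtn (-0.86), Hspb7 (-0.86), Pcp4l1 (-0.77) and Tph2, of serotonin synthesis (-0.65, adjusted p = 0.0405). Of 53 genes of the glutamatergic postsynapse, 3 rose and 50 did not pass, and 18 rose when adjusted over the list alone. The 3 were Grm5 (0.29), Gria3 (0.18) and Grin3a (0.24), which encode glutamate receptors. The list's mean log2 change was 0.10, fry gave an adjusted p of 0.00933, and camera's call was lost, at adjusted p = 0.346 with an estimated correlation. Of 44 voltage-gated channel genes, Cacna2d1 rose (0.21) and 43 did not pass, and 6 rose and 1 fell adjusted over the list alone (adjusted p = 0.598 with an estimated correlation). The mean of the channel list was 0.03, -0.01 without WT vehicle male 2 and 0.06 without WT vehicle male 1. No autism risk gene of 92 passed, with 17 rising adjusted over the list alone and adjusted p = 0.5 with an estimated correlation. Neither this list nor the postsynaptic list holds Shank2 itself. Of 26 astrocyte markers, Ntsr2 fell (-0.26) and 25 did not pass, and 2 fell adjusted over the list alone (adjusted p = 0.499 with an estimated correlation).

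Markers of striatal projection neurons had a mean log2 difference of -0.91 between HT and WT vehicle libraries, with 0 of 21 passing and 8 falling adjusted over the list alone (adjusted p = 0.5 with an estimated correlation). The 17 olfactory bulb markers had a mean of -0.34, with 0 passing, also adjusted over the list alone (adjusted p = 0.744 with an estimated correlation). The striatal mean difference was -0.58 without WT vehicle male 1, and the olfactory one -0.11 without WT vehicle female 1 and 0.07 with 2 surrogate variables. The striatal mean was 0.57 ± 1.33 in WT vehicle females and 0.24 ± 1.37 in WT vehicle males, against -0.50 ± 0.14 and -0.51 ± 0.08 in HT vehicle females and males. Of the 36 lists, camera called 21 in this comparison, 5 higher and 16 lower, fry called 2 and camera with an estimated correlation 0. With only the groups compared in the fit, 8 genes were called in place of 127. Leaving out any 1 of 14 of the 18 libraries moved the count of 127 genes by over 1.5 times, from 34 without HT vehicle female 5 to 394 without WT vehicle male 1. Without WT vehicle male 2 it was 48, of which 39 were among the 127, and Grm5, Gria3, Grin3a, Tll2, Pcdha1, Trpc5, Nrtn, Tph2 and Ntsr2 no longer passed; of 27 named called genes, 7 passed with every library left out in turn, namely Shank2, Gm26793, Bc1, Ccnd1, Hrk, Esr1 and Chrnb3, and 4 of the 7 also passed under every other setting.

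The strongest rise was that of Gm26793, a noncoding gene on chromosome 7 (144894560 to 144897461) annotated as antisense, which overlaps Fgf15 on the other strand. It went from 2.67 ± 2.33 in WT vehicle libraries to 70.7 ± 12.2 in HT vehicle libraries (log2 change 4.6 ± 0.32, adjusted p = 1.72e-15). The log2 change was 4.73 under fluoxetine and 4.29 under lithium. The strand setting of the counting is not given in the sources used here, so reads of Gm26793 and Fgf15 cannot be separated. Bc1, a short brain noncoding RNA (chromosome 7, 144914470 to 144914637), fell from 6229.9 ± 2844 to 2169 ± 1235 (log2 change -1.63 ± 0.27, adjusted p = 0.000913). Its HT against WT change was -1.17 under fluoxetine (adjusted p = 0.0336), and under lithium its value was -0.74 (adjusted p = 0.38). Ccnd1 fell under every treatment, with log2 changes of -0.70, -0.88 and -0.68 under vehicle, fluoxetine and lithium. Over all treatments, a comparison chosen after the data were seen, 8 of 26 tested genes within 1 Mb of Shank2 were called: Gm26793 (4.54), Bc1 (-1.18), Ccnd1 (-0.76), Tpcn2 (-0.50), Mrgprf (0.58), LTO1 (0.34), Cttn (0.12) and Cd81 (-0.06, adjusted p = 0.0498). LTO1 and Ccnd1 overlap on opposite strands, and their reads carry the same uncertainty.

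**Figure D2:**
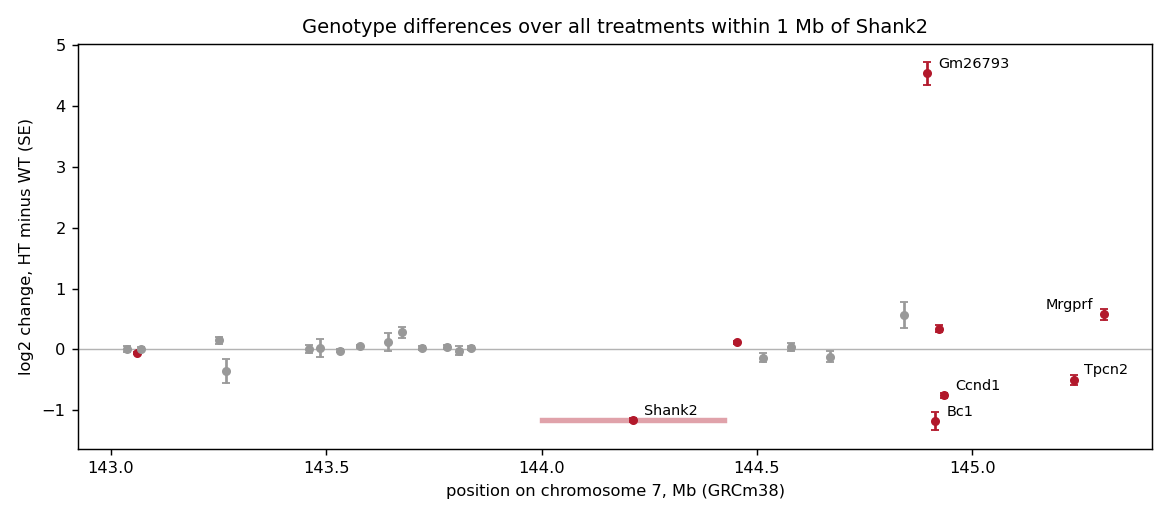
Log2 change from WT to HT over all treatments, with its standard error, against position on chromosome 7 in Mb (GRCm38), for genes within 1 Mb of Shank2; red points are called genes and the bar is the Shank2 gene. The called genes include Gm26793 at 4.54, Bc1 at -1.18 and Ccnd1 at -0.76.

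Within females, 4 genes separated HT from WT: Shank2 (-1.18), Gm26793 (4.34), Ccnd1 (-0.65 ± 0.10, adjusted p = 0.000478) and Hrk (0.51 ± 0.10, adjusted p = 0.0127). In males 668 genes were called, 486 higher and 182 lower. Those with the smallest adjusted p were the neuronal gene Nexmif (0.53), Dhx9 (0.34), Trpc5 (0.88), Cacna2d1 (0.37) and Srgap3 (0.34) among rises. Among falls they were Shank2 (-1.04), Ccnd1 (-0.76 ± 0.10, adjusted p = 8.29e-06), Lgals3bp (-0.61), Ntsr2 (-0.45) and Prdx6 (-0.35). The count in males was 5 with a term for the trend of each library with transcript length. With only the groups compared in the fit it was 3. Without WT vehicle male 2 it was 3, and then only Shank2 and Ccnd1 of these 10 still passed. The genotype effect itself did not differ between the sexes for any gene by limma (0 called, 2463 at an unadjusted p under 0.05).

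The libraries also differed in a trend with transcript length, measured per library as the rank correlation of its deviation from the mean of the other libraries with transcript length, across genes outside all lists. In HT the trend was -0.047 ± 0.053 under vehicle (n = 10), 0.019 ± 0.083 under fluoxetine (n = 10, two-sided permutation p = 0.0506, adjusted over 5 comparisons 0.0632) and 0.07 ± 0.071 under lithium (n = 10, permutation p = 0.00113, adjusted 0.00565). In WT it was -0.076 ± 0.114 under vehicle (n = 8), 0.023 ± 0.049 under fluoxetine (n = 10, two-sided exact permutation p = 0.0121, adjusted 0.0202) and 0.05 ± 0.075 under lithium (n = 9, exact permutation p = 0.00995, adjusted 0.0202). In WT vehicle male 2 the trend was -0.32, where the other WT vehicle libraries had -0.136 to 0.052. This library therefore weighs on the WT vehicle mean and SD, and the tests were not repeated without it. Above zero lay 1 of 8 WT vehicle libraries, 8 of 10 under fluoxetine and 7 of 9 under lithium. HT and WT vehicle libraries were not found to differ (exact permutation p = 0.525, adjusted 0.525). The median transcript length was 630.25 bases in the ribosomal list, 607 in the oxidative phosphorylation list, 2708 in the presynaptic list and 3146 in the channel list, against 1560 for all genes tested. With the trend as a term in the fit (the length term), a setting chosen after the data were seen, 160 genes were called for genotype, 123 of the 127 among them. The counts were 108 and 3 for fluoxetine and lithium in HT, and 0 and 67 in WT. Over the genes called without the term, the median change went from 0.253 to 0.235 for genotype, from 0.288 to 0.227 and from 0.252 to 0.147 for fluoxetine and lithium in HT, and from 0.267 to 0.156 and from 0.230 to 0.14 in WT. Every one kept its direction. The median standard error went from 0.063, 0.064, 0.058, 0.063 and 0.062 to 0.057, 0.058, 0.057, 0.055 and 0.062. Calls for fluoxetine in HT rose from 55 to 108. Those lost in the drug effects ended because the changes shrank. The trend goes with the drugs, so the fit cannot divide a change between drug and trend.

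In HT, the genes that fluoxetine lowered included some of the ribosome and of mitochondrial respiration. Rpl39, a ribosomal protein, fell from 1333 ± 147 under vehicle to 1007 ± 85.1 under fluoxetine (n = 10 each, log2 change -0.40 ± 0.08, adjusted p = 0.00968). Ndufs4, of respiratory complex I, fell from 1579 ± 142 to 1249 ± 113 (-0.34 ± 0.06, adjusted p = 0.00968). Kndc1, a brain guanine nucleotide exchange factor, rose from 2384 ± 115 to 2919 ± 279 (0.29 ± 0.06, adjusted p = 0.0203), and Grin2d, a glutamate receptor subunit, rose from 592 ± 53.2 to 725 ± 65.4 (0.29 ± 0.06, adjusted p = 0.0203).

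The comparison called 55 genes, 15 higher and 40 lower, with a median size of 0.288 (2429 genes at an unadjusted p under 0.05). Further rises were Usp54 (0.31), Sorbs3 (0.29), Inpp5b (0.28), Auts2 (0.26, adjusted p = 0.047), Foxred2 (0.24) and Nphp4 (0.22). Further falls were Gpr34, a receptor of microglia (-0.47, adjusted p = 0.0458), Rpl24 (-0.42), Tmem256 (-0.40), the splicing gene Snrpg (-0.39) and Plekho2 (-0.38). Of 80 cytosolic ribosomal protein genes, 9 fell and 71 did not pass, and 35 fell adjusted over the list alone; Rps21 (-0.36), Rpl41 (-0.30) and Rplp1 (-0.30) were among the 9. The list's mean log2 change was -0.14, with adjusted p = 0.499 with an estimated correlation and 0.103 by fry. Of 73 nuclear genes of oxidative phosphorylation, 7 fell and 66 did not pass, and 28 fell adjusted over the list alone; Atp5e (-0.38), Cox7a2 (-0.29), Ndufa2 (-0.29) and Atp5l (-0.21) were among them. Its mean was -0.12 (adjusted p = 0.5 with an estimated correlation). Of 24 microglial markers, Gpr34 fell and 23 did not pass, 8 fell adjusted over the list alone, and the mean was -0.20 (adjusted p = 0.5 with an estimated correlation), or -0.10 without HT fluoxetine male 3, whose own list mean was -1.02. No gene of the 28 for endoplasmic reticulum stress or the 26 for cholesterol synthesis passed, and 7 of each fell adjusted over the list alone (adjusted p = 0.5 and 0.508 with an estimated correlation).

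Striatal markers had a mean log2 difference of 0.71 and olfactory bulb markers of 0.52 (-0.02 with 2 surrogate variables) between these groups, with 0 of 21 and 0 of 17 passing, also adjusted over the lists alone (adjusted p = 0.557 and 0.509 with an estimated correlation). Camera called 17 of 36 lists, 7 higher and 10 lower, and both fry and camera with an estimated correlation called 0. Leaving out any 1 of 13 of the 20 libraries moved the count by over 1.5 times, from 19 without HT vehicle female 3 to 171 without HT vehicle male 2. Of 27 named called genes, 9 passed with every library left out in turn: Kndc1, Gm10177 (-0.46, a predicted gene that may share reads), Tmem256, Rpl39, Ndufs4, Cox7a2, Ndufa2, Atp5l and Rpl41. Of the 9, 8 passed under every other setting too. With the length term 36 of the 55 genes remained called, and 4 ribosomal protein genes and 6 of oxidative phosphorylation fell, with list means of -0.06 and -0.05.

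In HT, the genes lower under lithium included ribosomal protein genes, and nearly all calls were lost with the length term. Rps21 fell from 2323 ± 287 to 1682 ± 241 (n = 10 each, log2 change -0.47 ± 0.08, adjusted p = 0.00274). Ddit4, an inhibitor of the growth regulator mTORC1 that glucocorticoids induce, fell by 0.40 on the log2 scale (adjusted p = 0.0142). Cebpd, a transcription factor, fell from 107 ± 12.4 to 73.4 ± 19.4 (-0.56 ± 0.12, adjusted p = 0.0106). Utp14b, of ribosome assembly, rose from 340.4 ± 42.1 to 463 ± 57.4 (0.44 ± 0.10, adjusted p = 0.0142), and Slfn3 rose by 0.84 (adjusted p = 0.0213).

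Of 148 called genes, 31 were higher and 117 lower, with a median size of 0.252 (2137 at an unadjusted p under 0.05). Further rises were Slfn9 (0.72), the matrix proteoglycan Lum (0.67), Ddx4 (0.47), the kinase Plk3 (0.43) and the transcription factor Mycn (0.42). Further falls were Depp1, a target of FOXO factors (-0.96 ± 0.23, adjusted p = 0.025), Tmem252 (-0.66), Zfp189 (-0.55), Plekhf1 (-0.52) and Smox, of polyamine breakdown (-0.44). Of the 80 ribosomal protein genes, 24 fell and 56 did not pass, and 55 fell adjusted over the list alone. Rps15a (-0.37), Rpl37 (-0.39) and Rps28 (-0.40) were among them. The mean was -0.17, fry gave an adjusted p of 0.0168, and camera gave adjusted p = 0.346 with an estimated correlation. Of 23 glucocorticoid targets, 3 fell (Cebpd, Ddit4 and Nfkbia at -0.33) and 20 did not pass, and 5 fell adjusted over the list alone (fry adjusted p = 0.103, and adjusted p = 0.5 with an estimated correlation). Of the 73 oxidative phosphorylation genes, Ndufa2 (-0.29), Ndufs4 (-0.28) and Uqcrq (-0.26) fell, 70 did not pass, and 9 fell adjusted over the list alone (adjusted p = 0.557 with an estimated correlation). Of 30 immediate early genes, Dusp6 rose (0.37), 29 did not pass, and 2 rose adjusted over the list alone (adjusted p = 0.5 with an estimated correlation). No cholesterol gene of 26 passed, and 8 rose adjusted over the list alone, with a mean of 0.12 (adjusted p = 0.499 with an estimated correlation).

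Camera called 7 lists, 4 higher and 3 lower, fry 1 and camera with an estimated correlation 0. Leaving out any 1 of 9 of the 20 libraries moved the count by over 1.5 times, from 56 without HT lithium female 5 to 226 without HT lithium female 1. Of 29 named called genes, 10 passed with every library left out in turn: Utp14b, the predicted gene Gm12070 (-0.84), Cebpd, Zfp189, Rps21, Ndufa2, Rps15a, Rpl37, Rps28 and Ddit4. None of the 10 passed under every other setting. With the length term 1 of the 148 genes remained called, no ribosomal protein gene was called, the ribosomal list mean went from -0.17 to -0.03 and that of oxidative phosphorylation from -0.08 to 0.04.

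In WT, the genes that fluoxetine lowered included ribosomal, respiratory and red blood cell genes, and most of these calls were lost without WT vehicle male 2 and all with the length term. Rpl13a fell from 5470.2 ± 937 (n = 8) to 4233 ± 279 (n = 10), a log2 change of -0.36 ± 0.06 (adjusted p = 0.00288). Chchd1, of the mitochondrial ribosome, fell from 383 ± 69.0 to 275 ± 33.3 (-0.47 ± 0.08, adjusted p = 0.00288). The adult beta-globin gene Hbb-bs fell from 4306 ± 1569.6 to 2114 ± 759 (-1.03 ± 0.22, adjusted p = 0.0166). Zbtb16, a transcription factor that glucocorticoids induce, rose by 0.65 (adjusted p = 0.0436).

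The comparison called 140 genes, 54 higher and 86 lower, with a median size of 0.267 (2538 at an unadjusted p under 0.05). Further rises were Runx1 (0.66), Pakap (0.66), Iqcg (0.60), Fmn1 (0.41), the neurotensin receptor Ntsr1 (0.40) and Cdc73 (0.39). Further falls were Sap25 (-1.0), Rpl24 (-0.51), Atp5e (-0.43) and Cbr3 (-0.43). Of 10 blood genes, 4 fell and 6 did not pass, and 6 fell adjusted over the list alone. Besides Hbb-bs these were Hbb-bt (-1.09), Hba-a1 (-0.93) and Alas2, of heme synthesis (-0.87); the globin copies share sequence and their values are uncertain one by one. The mean was -0.53, fry gave an adjusted p of 0.00643 and camera gave adjusted p = 0.312 with an estimated correlation. Of the 80 ribosomal protein genes, 22 fell and 58 did not pass, and 62 fell adjusted over the list alone; Rpl41 (-0.35), Rpl17 (-0.24) and Rpl36 (-0.35) were among the 22. The mean was -0.20 (fry adjusted p = 0.0127, and adjusted p = 0.346 with an estimated correlation). Of the 73 oxidative phosphorylation genes, 13 fell, Cox7a2 (-0.29), Ndufs4 (-0.32) and Ndufb6 (-0.23) among them, 60 did not pass, and 37 fell adjusted over the list alone (adjusted p = 0.499 with an estimated correlation). Of 44 voltage-gated channel genes, 4 rose and 40 did not pass, and 15 rose adjusted over the list alone; the 4 were Kcnh7 (0.32), Scn2a (0.32), Kcna2 (0.25) and Cacna2d1 (0.19). Fry gave an adjusted p of 0.0269 for the channels, and camera adjusted p = 0.499 with an estimated correlation. Of 26 cholesterol genes, Fdps (-0.29) and Tm7sf2 (-0.22) fell, 24 did not pass, and 6 fell adjusted over the list alone (adjusted p = 0.5 with an estimated correlation). Dlgap1 (0.14) and Nlgn1 (0.21) rose among 53 postsynaptic genes, with 6 rising adjusted over the list alone (adjusted p = 0.5 with an estimated correlation).

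The olfactory list mean was 1.01 ± 0.27 in WT fluoxetine males and -0.66 ± 0.46 in WT fluoxetine females, and the striatal mean was -0.46 ± 0.13 and 0.95 ± 1.01. Camera called 16 lists, 8 higher and 8 lower, fry 3 and camera with an estimated correlation 0. Without WT vehicle male 2 the count of 140 was 5 and 34 of 37 named called genes no longer passed, the exceptions being Rpl13a, Chchd1 and Rpl41, of which 0 passed under every other setting. List means with the length term were -0.08 for ribosomal proteins, -0.035 for oxidative phosphorylation, 0.04 for the channels and -0.545 for blood. The mean change went from -0.14 to -0.08 for oxidative phosphorylation, from -0.20 to -0.145 for ribosomal proteins, from 0.115 to 0.08 for the channels and from 0.06 to 0.03 for the postsynapse when this library was left out. Its own oxidative phosphorylation and ribosomal means were 0.570 and 0.591, where the other WT vehicle males had 0.062 to 0.0748 and 0.125 to 0.226. Leaving out any 1 of 11 of the 18 libraries moved the count of 140 by over 1.5 times, up to 563 without WT vehicle male 1. With only the groups compared in the fit it was 2.

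Lithium in WT gave the largest count of the 5 effects over both sexes, with ion channel and presynaptic genes among the rises and ribosomal protein genes among the falls, calls that were lost for all of these genes with the length term. The potassium channel gene Kcna1 rose from 1741 ± 459 (n = 8) to 2651 ± 331 (n = 9), a log2 change of 0.65 ± 0.12 (adjusted p = 0.00124). Syt2, a calcium sensor of fast transmitter release, rose from 615 ± 107 to 999 ± 111 (0.71 ± 0.16, adjusted p = 0.00481). Ctnnb1, which encodes beta-catenin, a substrate of the lithium-inhibited kinase GSK3, fell from 21595 ± 2139 to 18484 ± 1157 (-0.22 ± 0.04, adjusted p = 0.00143). Rpl17 fell by 0.28 (adjusted p = 0.000444).

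Of 1421 called genes, 908 were higher and 513 lower, with a median size of 0.230 (3965 at an unadjusted p under 0.05). Of 44 voltage-gated channel genes, 14 rose and 30 did not pass, and 20 rose adjusted over the list alone. Kcnma1 (0.31), Kcna2 (0.33) and Scn2a (0.38) were among them; the mean was 0.13, with a fry adjusted p of 0.0127 and adjusted p = 0.499 with an estimated correlation. Of 49 presynaptic genes, 15 rose and 34 did not pass, 19 rose adjusted over the list alone, and Rab3c (0.28) and Sv2b (0.24) were examples (fry adjusted p = 0.0264, and adjusted p = 0.499 with an estimated correlation). Of 53 postsynaptic genes, 10 rose and 43 did not pass, and 19 rose adjusted over the list alone; Grm5 (0.30), Cyfip2 (0.19), Dlg2 (0.22) and Gria3 (0.17) were among the 10 (fry adjusted p = 0.0446, and adjusted p = 0.5 with an estimated correlation). Of 80 ribosomal protein genes, 51 fell and 29 did not pass, and 68 fell adjusted over the list alone; Rpl13a (-0.35), Rps14 (-0.35) and Rps18 (-0.29) were examples. The mean was -0.21 (fry adjusted p = 0.00664, and adjusted p = 0.461 with an estimated correlation). Of 92 autism risk genes, 12 rose, 3 fell and 77 did not pass, and 24 rose and 5 fell adjusted over the list alone, with the kinase Dyrk1a at 0.20 (adjusted p = 0.509 with an estimated correlation). Of 26 cholesterol genes, 4 rose, Hsd17b7 (0.27) and Sc5d (0.24) among them, and 22 did not pass, and 4 rose adjusted over the list alone (adjusted p = 0.652 with an estimated correlation). Of 23 glucocorticoid targets, Zbtb16 rose (0.70), Ddit4 (-0.41), Mt1 (-0.44) and Mt2 (-0.46) fell, and 19 did not pass; 1 rose and 5 fell adjusted over the list alone (adjusted p = 0.652 with an estimated correlation). Of 26 astrocyte markers, 5 fell and 21 did not pass, and 6 fell adjusted over the list alone; Apoe (-0.21), Id3 (-0.28), S100b (-0.22) and Htra1 (-0.29) were among the 5 (adjusted p = 0.557 with an estimated correlation).

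Among the largest changes of single genes, Olfr316 rose (0.97 ± 0.23, adjusted p = 0.00682), and Apoc1 (-1.02), Depp1 (-0.86) and Lgals4 (-0.77) fell. Fam205a2 (4.06), Gm49450 (1.53) and the pseudogene Rpl14-ps1 (4.17) also rose, but may share reads with near copies and are uncertain. Gm18588 was called higher and was listed at 0 in WT vehicle libraries. Striatal markers had a mean log2 difference of -0.46 (-0.13 without WT vehicle male 1, -0.22 without WT vehicle female 4) and 0 of 21 passed, also adjusted over the list alone (adjusted p = 0.794 with an estimated correlation). Camera called 14 lists, 6 higher and 8 lower, fry 4 and camera with an estimated correlation 0. With only the groups compared in the fit, 204 genes were called in place of 1421. Leaving out any 1 of 5 of the 17 libraries moved the count by over 1.5 times; it ran from 796 without WT lithium female 4 to 1979 without WT vehicle male 1, and was 909 without WT vehicle male 2, with 741 of these among the 1421. Of 60 called genes picked by the naming rule, 30 passed with every library left out in turn, Kcna1, Syt2, Ctnnb1, Scn2a, Ddit4 and Rpl17 among them, and 2 of the 30, Ddit4 and Olfr316, passed under every other setting too. With the length term 53 of the 1421 genes remained called, and the list mean was 0.04 for channels, 0.07 for the presynapse, 0.04 for the postsynapse, -0.065 for ribosomal proteins, 0.07 for oxidative phosphorylation, 0.002 for glucocorticoid targets and -0.02 for autism risk genes. WT vehicle male 2 had list means of -0.386 for channels, -0.172 for the presynapse, -0.289 for the postsynapse and 0.591 for ribosomal proteins, so its values lay in the direction of these changes. Without it the mean change went from 0.13 to 0.09 for channels, from 0.11 to 0.095 for the presynapse, from 0.085 to 0.06 for the postsynapse, from 0.07 to 0.03 for autism risk genes and from -0.21 to -0.16 for ribosomal proteins.

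**Figure D3:**
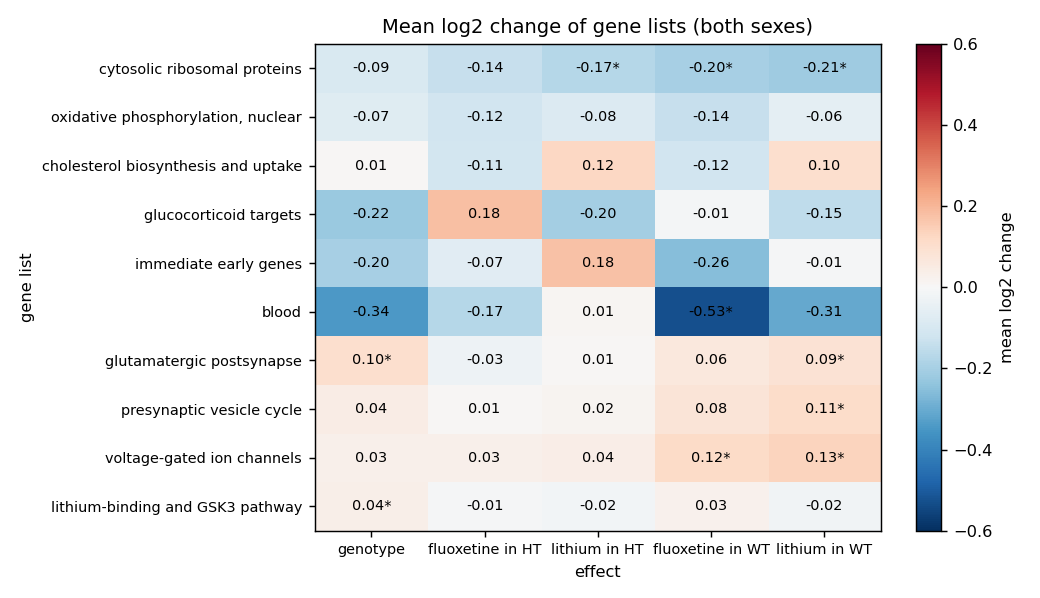
Mean log2 change of 10 gene lists in the 5 effects over both sexes; a star marks a fry adjusted p under 0.05. The ribosomal list lies below 0 in all 5 effects, at -0.14 and -0.17 for fluoxetine and lithium in HT and -0.20 and -0.21 in WT.

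Within a single sex, drug effects in HT passed for 1 gene. Pnck, a brain calmodulin-dependent kinase, fell in HT females under lithium (-0.41 ± 0.08, adjusted p = 0.0369), a call kept in 4 of 10 fits that each left out a library and lost with the length term. By limma 0 genes were called for fluoxetine in HT females, for either drug in HT males and for lithium in WT females, with 1565, 1469, 1500 and 1227 genes at an unadjusted p under 0.05. Fluoxetine in WT females called Igsf8 (0.37), Ntsr1 (0.75) and Nrf1 (-0.49), each at an adjusted p of 0.0362 each kept in 2 of 9 such fits and each lost with the length term.

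In WT males both drugs called many genes. Lithium called 1698, 1061 higher and 637 lower. Pnck fell there too (-0.55 ± 0.08, adjusted p = 0.00012), as did the calcium sensor Hpca (-0.45), Tmem91 (-0.59), Fam173a (-0.39) and Rpl17 (-0.37). Ankrd42 (0.56), Mta3 (0.42), Dhx9 (0.38), Pcdha1 (0.93) and the motor protein gene Myo5a (0.58) rose. All 10 passed with every library left out in turn. With only the groups compared 1 gene was called, and none of the 10 passed. The count was 133 without WT vehicle male 2 and 2 with the length term, where 1655 of 1698 kept direction. Fluoxetine in WT males called 472 genes, 261 higher and 211 lower. Zbtb16 (1.22), Steap2 (0.69), Thoc2 (0.36), U2surp (0.33) and Thrap3 (0.30) rose. The oligodendrocyte factor Sox8 (-0.54), the immediate early gene Junb (-1.1), Gpx4 (-0.41), Rilpl2 (-0.44) and Fam174a (-0.33) fell. The count was 0 without WT vehicle male 2, and none of these 10 passed. It was 11 with the length term and 5 with only the groups compared.

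The fluoxetine effect in WT differed between the sexes in 422 genes, 149 with a higher and 273 with a lower change in females than in males. Sox8 had the smallest adjusted p, with a female minus male difference of 0.80 ± 0.13 (adjusted p = 0.003). Igsf8 (0.52), the calcium channel gene Orai3 (0.50), Cdh9 (1.14) and Slain1 (0.60) were also higher. The incretin receptor gene Gipr (-2.07), Pappa (-2.7), Steap2 (-0.96), Igsf3 (-0.92) and Acan, of perineuronal nets (-1.75), were lower. The olfactory and striatal list means of the WT fluoxetine libraries lay apart by sex, as given above, and the mean change of the myelinating oligodendrocyte list was 0.46 in females and -0.36 in males. The count was 0 with both list means as terms, 1 without WT vehicle female 1 and 8 without WT vehicle male 2. With only the groups compared in the fit it was 1. For the other effects limma called 0 genes as different between the sexes, with 2463 genes for genotype, 615 for fluoxetine in HT, 578 for lithium in HT and 1326 for lithium in WT at an unadjusted p under 0.05. Neither drug effect differed between HT and WT in any gene by limma, with 1285 genes for fluoxetine and 1218 for lithium at an unadjusted p under 0.05. Counts of called genes that differ between HT and WT, or between the sexes under lithium, therefore come without a gene whose difference passed. In simulated data of this size the fit found 19.4% of changes of 0.25 and 70.1% of changes of 0.5 in the genotype difference of fluoxetine. In that of lithium it found 23.9 and 56.7%. These shares may be too high, since the simulated residuals spread less than the data.

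**Figure D4:**
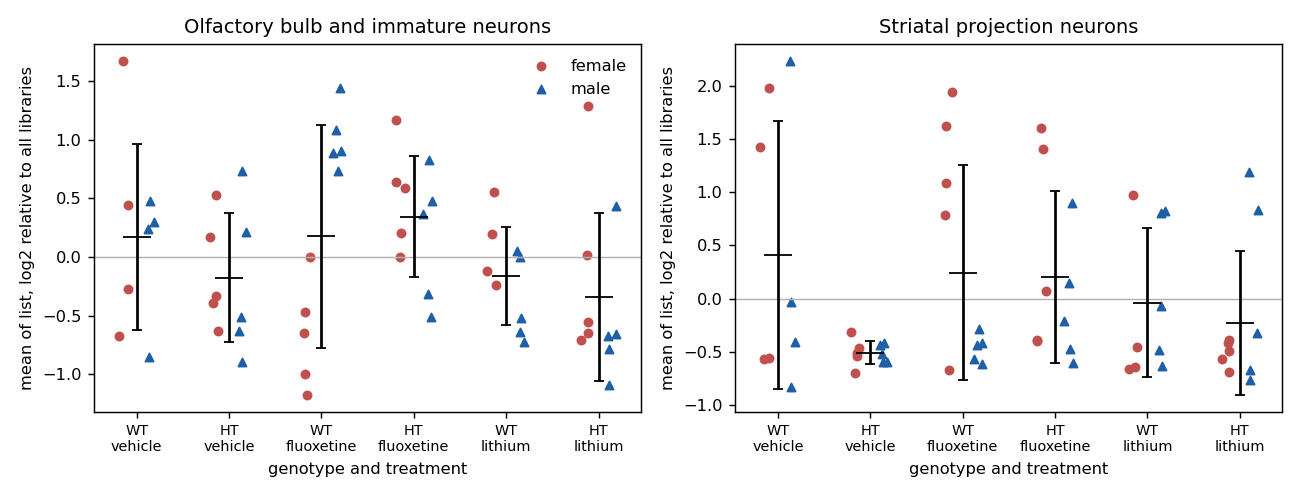
Mean log2 value of the olfactory bulb list and of the striatal list in each of the 57 libraries, by group, relative to the mean over all libraries. The olfactory mean is 1.01 ± 0.27 in WT fluoxetine males and -0.66 ± 0.46 in WT fluoxetine females.

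Whether a drug ran against the genotype effect in HT was measured as a correlation across genes, which are not independent replicates, with the HT vehicle libraries split so that no library entered both effects. For fluoxetine the correlation was -0.093, where simulated data without effects gave 0.003 ± 0.102. Its covariance was -0.00422, against a simulated 6.59e-05. For lithium the correlation was 0.073, where simulation gave 0.004 ± 0.107, with a covariance of 0.00322 against 0.000117. With all HT vehicle libraries in both effects the values were -0.385 and -0.200, where shared libraries alone gave -0.463 ± 0.104 and -0.456 ± 0.112 in simulation, so the value for lithium lay above the simulated mean by more than its spread. With the libraries split, neither drug effect in HT ran with or against the genotype effect by more than the simulated spread.

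The effects of a drug in HT and in WT share no library. Their correlation across genes was 0.231 for fluoxetine, within the simulated range of -0.242 to 0.314, and 0.343 for lithium, above the simulated range of -0.293 to 0.318. The value for lithium fell within that range in several settings: 0.293 with 2 surrogate variables, 0.271 without the 3 libraries of lowest correlation, 0.3 with dissection terms, 0.22 with both, 0.266 without WT vehicle male 2, and 0.291 to 0.315 without HT vehicle male 1, male 5 or female 4, or HT lithium male 3, female 3 or female 4. That range was simulated from all libraries without added terms and was not computed again for these settings, so the comparison is rough. In females alone the correlations were 0.018 for fluoxetine and 0.056 for lithium, and in males alone 0.186 and 0.328. Of the genes fluoxetine lowered, 40 in HT and 86 in WT, 21 were lowered in both, where independent lists would share 0.21. Without WT vehicle male 2 these numbers were 137 in HT, 4 in WT and 4 in both, and with the length term 87, 0 and 0. Of the 21, Ndufs4, Cox7a2, Atp5e, Rpl13a, Rpl39 and Rps21 are examples. No gene was raised by fluoxetine in both, where 0.05 would be by chance. Lithium lowered 61 genes in both genotypes, where independent lists would share 3.6, including Ctnnb1, Ddit4, Depp1, Frat1, Mapk3, Pnck and Smox. It raised 15 in both, where independent lists would share 1.69, including Plk3, Slfn9, Spry4 and Scd1. Without WT vehicle male 2 lithium lowered 58 and raised 22 in both, and with the length term it lowered 1 and raised 0. All 117 genes that lithium lowered in HT had a negative change in WT, called or not. Ribosomal and respiratory genes move together, so shared genes are not independent of each other. Fluoxetine and lithium correlated at 0.044 in HT and 0.158 in WT with the vehicle libraries split, where simulation gave -0.003 ± 0.106 and -0.001 ± 0.093; with shared vehicle libraries the values were 0.376 and 0.695, against 0.486 ± 0.105 and 0.540 ± 0.089 in simulation.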

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

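The 8 measures per library that were searched for libraries standing apart, and the tests of transcript length and of mislabelling given here, were chosen after the library values had been seen; the tests of the sex difference and of tissue in WT vehicle male 2 were written down before their results.

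The fluoxetine effect in WT differed between females and males in 422 genes, Sox8, Gipr, Pappa and Acan among them, and 1 of 100 splits of the labels, the real one, gave as many (highest other split 135). A response of the sexes shared by both genotypes is argued against: over these genes the median sex difference in HT, turned to the WT direction, was -0.026, and 178 of 422 had the same sign. Olfactory and striatal tissue in the samples may account for it, since with both list means as terms 0 genes were called; the median change went from 0.605 to 0.337 and the median standard error from 0.151 to 0.148, so the calls ended because the changes shrank, while 421 of 422 kept their direction. A dependence on 1 library stays open too, with 1 gene called without WT vehicle female 1 and 8 without WT vehicle male 2. The myelinating oligodendrocyte list also moved apart, by 0.462 in females and -0.363 in males. A difference in that cell type stays open, as does a sex-specific response of WT mice to fluoxetine, not tested apart from these.

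WT vehicle male 2 had the lowest median correlation with the other libraries, 0.968 (group 0.984 to 0.985). Its Shank2 value of 6762 was the lowest in WT. A sample mislabelled in sex or genotype is argued against: its Gm26793 value was 0 (HT 37.5 to 100, other WT 0 to 6.66). Its Ddx3y value of 1209 lay within the males' 1032 to 1707. Olfactory and striatal tissue as the whole explanation is argued against as well, because its correlation stayed the lowest, at 0.969, with both list means removed (others 0.972 to 0.988). RNA fragmentation or another bias by transcript length is a candidate explanation: its deviation from the mean of all other libraries had a rank correlation of -0.331 with transcript length across genes, where other libraries had -0.151 to 0.173. A wrong treatment label and biological explanations were not tested.

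Other libraries stood apart from their group in single measures. HT fluoxetine male 3 had a rough estimate of 24.0 M reads (M, mega), where its group had 32.7 to 35.7 M, and a median correlation of 0.970, where its group had 0.985 to 0.986. Its Shank2 value was 3877, where its group had 4439 to 4535. Shank2 in HT fluoxetine female 1 was 4814, where its group had 3943 to 4147. The median correlation was 0.981 in HT fluoxetine female 4 (group 0.984 to 0.985), 0.983 in HT vehicle female 2 (group 0.985 to 0.986) and 0.977 in WT vehicle female 1 (group 0.984 to 0.985). The olfactory list mean of HT lithium male 2 was 0.432, where its group had -1.09 to -0.653, and the striatal list mean of WT lithium female 1 was 0.971, where its group had -0.657 to -0.458. In all, 96 combinations of measure and group were searched and 10 stood out, where chance alone marks about 5%.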

How the results depend on the processing

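Settings without 3 libraries, with dissection terms, with both, and with the length term, were chosen after the data had been seen, as were the 3 comparisons over all treatments or both genotypes; the other settings were planned. Planned fits of count models, with their size factors, filter on low counts and surrogate variables, were not run because the table holds no counts. Shank2 stayed lower in HT and called under every setting run, with a log2 change of -1.18 (without WT vehicle male 2) to -1.08 (without WT vehicle male 3) when a library was left out. Of 289 called values of named genes, 38 passed under every setting and with every library of the groups compared left out, and 2 changed sign, both with the length term: Gm37593 (-0.098) and Gm43462 (-0.019) in lithium over both genotypes. With that term 1980 of the 2216 called there kept their direction. Counts of called genes depended far more on the setting: the pseudocount moved no count by over 1.5 times, trimmed-mean scaling moved 1, and fitting only the groups compared moved 11. Of the counts over all treatments or both genotypes, those for fluoxetine moved by over 1.5 times without a filter on low values and without WT vehicle female 1 (1288), WT vehicle male 1 (1194) or WT vehicle male 2 (486), and both drugs with the length term. The causes of the moved values were not tested. Fewer libraries, fewer groups or more genes tested by construction change the error and the adjustment, but by how much was not measured. A fit of only the groups compared takes the spread from these groups alone, and whether groups differ in spread was not tested. Depth limits low genes most, since roughly estimated depths of 24.0 to 37.1 M reads (M, mega) leave few reads for a gene near the minimum mean of 10.

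Without a filter on low values the calls numbered 64 for genotype, 23 and 79 for fluoxetine and lithium in HT, and 41 and 884 in WT. In females they were 16 for genotype, 0 for lithium in HT, and 19 and 1 for fluoxetine and lithium in WT. In males they were 231 for genotype, and 163 and 1124 for the drugs in WT. The sex difference in fluoxetine in WT had 139 and fluoxetine over both genotypes 469. With a minimum mean of 50, fluoxetine in HT had 93, lithium in HT females 5 and fluoxetine in WT females 6. Trimmed-mean scaling gave 0 for lithium in HT females.

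With 2 surrogate variables there were 42 for genotype, and 155 and 62 for fluoxetine in HT and in WT. In females there were 8 for lithium in HT, and 0 and 2 for fluoxetine and lithium in WT. In males there were 3 for genotype, 33 and 15 for the drugs in HT, and 0 and 304 in WT. The sex difference in fluoxetine in WT had 0. The correlation of fluoxetine and lithium in WT was then 0.310. Fitting only the groups compared gave 8 for genotype, 2 for fluoxetine in WT, 204 for lithium in WT, 0 for lithium in HT females, 1 for fluoxetine in WT females, 3 for genotype in males, 33 for lithium in HT males, 5 for fluoxetine in WT males, 1 for lithium in WT males, 1 for the sex difference in genotype and 1 for that in fluoxetine in WT.

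The 3 libraries left out were WT vehicle male 2, HT fluoxetine male 3 and WT vehicle female 1. There were then 59 for genotype, 202 and 438 for fluoxetine and lithium in HT, and 13 and 834 in WT. In females there were 15 and 54 for the drugs in HT and 1 for lithium in WT. In males there were 10 for genotype, and 1 and 295 for the drugs in WT. The sex difference in fluoxetine in WT had 1 and the genotype difference in lithium 1. Dissection terms gave 57 for genotype, 253 for fluoxetine in WT, 5 for lithium in HT females, 0 for fluoxetine in WT females, 3 for lithium in WT females, 3 for fluoxetine in HT males, 29 for fluoxetine in WT males and 0 for the sex difference in fluoxetine in WT, and a correlation of fluoxetine and lithium in WT of 0.264. Both together gave 55 for genotype, 94 for fluoxetine in HT, 679 for lithium in HT and 48 for fluoxetine in WT. In females both gave 13 for genotype, 4 and 89 for fluoxetine and lithium in HT, and 0 and 10 in WT. In males both gave 7 for genotype, 1 and 3 for the drugs in HT, and 0 and 493 in WT. They gave 0 for the sex difference in fluoxetine in WT and 1 for the genotype difference in lithium. The correlations were then 0.220 between lithium in HT and in WT and 0.353 between fluoxetine and lithium in WT.

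The length term gave 108 (up from 55) and 3 for fluoxetine and lithium in HT, 0 and 67 in WT, and 77 and 169 over both genotypes. In females it gave 0 for lithium in HT, and 0 and 1 for the drugs in WT. In males it gave 5 for genotype, 4 for fluoxetine in HT, and 11 and 2 for the drugs in WT. The other counts stayed within 1.5 times, among them 160 for genotype and 308 for the sex difference in fluoxetine in WT. In the drug effects the changes shrank more than their errors. The trend goes with the drugs, and whether it comes from RNA quality or from the drugs was not tested.

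Replicate numbers are shared by the groups, but do not pair the libraries: of 44 pairs of the same number 2 had a correlation of deviations over 0.1, the mean was -0.031 against 0.008 for other numbers, and 6 of 44 libraries matched best with their own number. These are the numbers in the titles; 3 WT vehicle females have other numbers in the library names, by which 0 of 43 pairs had a correlation over 0.1, the mean was -0.049 against 0.012, and 5 of 43 matched best. With the number in the title as a block the calls were 47 for fluoxetine in WT, 2 for lithium in HT females, 0 for fluoxetine in WT females, 436 for genotype in males and 250 for fluoxetine in WT males; no other count of genes moved by over 1.5 times.

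Of 75 calls of lists by camera, 0 held with an estimated correlation and 9 passed by fry. With shared vehicle libraries in both effects the correlations were -0.385 and -0.200 for genotype with fluoxetine and lithium in HT, and 0.376 in HT and 0.695 in WT between the drugs, where shared libraries alone gave -0.463 ± 0.104, -0.456 ± 0.112, 0.486 ± 0.105 and 0.540 ± 0.089 in simulation. In males alone the correlation was 0.041 for genotype with fluoxetine in HT, and -0.095 in HT and 0.015 in WT between the drugs, while the drugs in HT and in WT kept 0.186 for fluoxetine and 0.328 for lithium. In females alone it was 0.018 for fluoxetine in HT and in WT, 0.056 for lithium in HT and in WT, and 0.063 between the drugs in WT. List means that changed sign, for which the cause was not tested, were in genotype the myelinating oligodendrocytes (0.046 with dissection terms, 0.097 with these and without 3 libraries), the olfactory bulb list (0.073 with 2 surrogate variables) and the voltage-gated channels (-0.005 with 2 surrogate variables, -0.019 without 3 libraries, -0.011 without WT vehicle male 2, against a highest value with a library left out of 0.062 without WT vehicle male 1). In fluoxetine in HT they were the myelinating oligodendrocytes (-0.081 with dissection terms, -0.009 with these and without 3 libraries) and the olfactory bulb list (-0.024 with 2 surrogate variables), and in lithium in WT oxidative phosphorylation (0.003 without WT vehicle male 2, the lowest with a library left out being -0.082 without WT vehicle male 1). Those turned by the length term were the chromatin modifiers (-0.006 for fluoxetine in HT, -0.017 for fluoxetine and -0.053 for lithium in WT), oxidative phosphorylation (0.04 for lithium in HT, 0.071 in WT), and in lithium in WT the glucocorticoid targets (0.002) and autism risk genes (-0.019). The olfactory and striatal lists have no value under dissection terms, which remove them by construction.

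Leaving out 1 library at a time gave 34 (without HT vehicle female 5) to 394 (WT vehicle male 1) for genotype, 19 (HT vehicle female 3) to 171 (HT vehicle male 2) for fluoxetine in HT, 56 (HT lithium female 5) to 226 (HT lithium female 1) for lithium in HT, 5 (WT vehicle male 2) to 563 (WT vehicle male 1) for fluoxetine in WT, and 796 (WT lithium female 4) to 1979 (WT vehicle male 1) for lithium in WT. Within females it gave 3 (HT vehicle female 2) to 9 (WT vehicle female 2) for genotype, 0 to 41 (HT lithium female 1) for lithium in HT, 0 to 177 (WT vehicle female 2) for fluoxetine in WT and 0 to 1 (WT lithium female 2) for lithium in WT. Within males it gave 3 (WT vehicle male 2) to 1725 (WT vehicle male 1) for genotype, 0 to 1 (HT vehicle male 4) for fluoxetine in HT, 0 (WT vehicle male 2) to 1410 (WT vehicle male 3) for fluoxetine in WT and 133 (WT vehicle male 2) to 2504 (WT vehicle male 1) for lithium in WT. For the sex difference it gave 0 to 89 (WT vehicle male 1) in genotype and 1 (WT vehicle female 1) to 1359 (WT vehicle male 3) in fluoxetine in WT. The genotype differences ran from 0 to 1 (WT vehicle female 4) for fluoxetine and 0 to 2 (WT vehicle male 2) for lithium, and fluoxetine over both genotypes from 486 (WT vehicle male 2) to 1288 (WT vehicle female 1).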

Other observations

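The comparisons over all treatments or both genotypes, and the tests of genes beside Shank2, were chosen after the results had been seen; the redrawn splits of the labels were not.

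Averaged over vehicle, fluoxetine and lithium, HT and WT differed in 623 genes, 270 higher and 353 lower in HT (highest other of 100 splits 2). Single genes among the falls, picked from several lists and not tested as a group, were Syt2 (-0.61 ± 0.09, adjusted p = 6.28e-06), the sodium channel subunit Scn4b (-0.73), Pvalb, which encodes parvalbumin (-0.35 ± 0.07, adjusted p = 0.00143), Cplx1 (-0.23), Vamp1 (-0.20), the potassium channel gene Kcnc1 (-0.13) and Hapln4 of perineuronal nets (-0.24). Striatal tissue stays open as a source of these: its list had the lowest mean, -0.38 (0 of 21 passed, fry adjusted p = 0.191). Of 49 presynaptic genes 3 fell and 46 did not pass, with 1 rising and 4 falling adjusted over the list alone (fry adjusted p = 0.89). Of 44 channel genes 2 rose, 5 fell and 37 did not pass, with 5 rising and 7 falling adjusted over the list alone (fry adjusted p = 0.539). Of 46 genes of GABAergic signalling, 5 fell, 1 rose (Vip, 0.21) and 40 did not pass, and 8 fell and 1 rose adjusted over the list alone (fry adjusted p = 0.0429, and adjusted p = 0.423 with an estimated correlation). Of 23 glucocorticoid targets, 7 fell, Tsc22d3 (-0.30), Mt2 (-0.32) and Nfkbia (-0.25) among them, and 16 did not pass, with 10 falling adjusted over the list alone (fry adjusted p = 0.0136, and adjusted p = 0.377 with an estimated correlation). Of 26 astrocyte markers, 6 fell, such as Gjb6 (-0.28) and Acsbg1 (-0.18), and 20 did not pass; 13 fell adjusted over the list alone (fry adjusted p = 0.0166, and adjusted p = 0.417 with an estimated correlation). Of 53 postsynaptic genes 6 rose, Grin3a (0.14) and Lrrtm1 (0.13) among them, and 47 did not pass, with 15 rising adjusted over the list alone (fry adjusted p = 0.0204, and adjusted p = 0.420 with an estimated correlation). Fry also called falls of the lysosome (adjusted p = 0.00312; 3 of 44 fell, 4 adjusted over the list alone), endothelial cells (0.0310; 5 of 22 and 9), interferon response (0.0310; 1 of 29 and 2), oxidative phosphorylation (0.0333; 3 of 73 and 29) and mitochondrial mRNAs (0.0429; 3 of 13 and 7), and a rise of the GSK3 pathway (0.00536; 1 of 23 and 2). Of 30 myelinating oligodendrocyte genes 1 fell, and 14 adjusted over the list alone (fry adjusted p = 0.0631). None of these lists passed with an estimated correlation (adjusted p of at least 0.266). Rises of single genes were Cfap46 (0.78), Apoc1 (0.72), Lrrc27 (0.58), Mrgprf (0.58), Myo1h (0.46) and Grp (0.46). Of these, Mrgprf, Cfap46 and Lrrc27 lie on chromosome 7, at 876.3, 4318.1 and 4758.9 kb from Shank2. Further falls were Chrnb3 (-0.97), Clic6 (-0.96), Jaml (-0.89), Krt80 (-0.75) and Ighm (-0.58). Without any 1 library the count ran from 501 to 872, and with the length term it was 709, 601 of the 623 among them.

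Averaged over both genotypes, lithium changed 2216 genes, 1193 higher and 1023 lower (highest other split 3). With the length term 169 genes were called, 93 of the 2216 among them. Of the 2216, 1980 kept their direction, and the median change went from 0.162 to 0.075 (median standard error 0.043 and 0.048). Then 3 ribosomal protein genes fell, and 1 presynaptic and 0 channel and cholesterol genes rose. The glucocorticoid target mean went from -0.18 to -0.03. Of 44 channel genes 15 rose, with Kcna1 at 0.45, and 29 did not pass, with 18 rising and 1 falling adjusted over the list alone (fry adjusted p = 0.0152, and adjusted p = 0.423 with an estimated correlation). Of 80 ribosomal protein genes 66 fell and 14 did not pass, with 72 falling adjusted over the list alone (fry adjusted p = 7.24e-05, and adjusted p = 0.192 with an estimated correlation). Of 26 cholesterol genes 9 rose and 17 did not pass, with 12 rising and 1 falling adjusted over the list alone (fry adjusted p = 0.0310, and adjusted p = 0.468 with an estimated correlation). Fry also called a rise of the presynapse (adjusted p = 0.0429; 11 of 49 rose, 19 adjusted over the list alone) and falls of glucocorticoid targets (0.0333; 7 of 23 and 9, with 1 rising by either count) and oligodendrocyte precursors (0.0492; 3 of 15 and 3), which did not pass with an estimated correlation (adjusted p of at least 0.468). Depp1 (-0.91), Cryba4 (-0.59), Dio3 (-0.48) and mt-Nd3 (-0.60) fell, and Slfn3 (0.73), F5 (0.68) and the clock gene Per2 (0.33) rose.

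Fluoxetine over both genotypes changed 791 genes, 280 higher and 511 lower (highest other split 3), although its simulated run called 113 unchanged genes. Without WT vehicle male 2, female 1 or male 1 the count was 486, 1288 or 1194. It was 469 without a filter on low values and 77 with the length term, 58 of the 791 among them. That term took the median change of the 791 from 0.172 to 0.107 (median standard error 0.044 and 0.043). With it 8 oxidative phosphorylation, 9 ribosomal protein, 5 immediate early, 1 blood, 1 cholesterol and 0 endoplasmic reticulum stress genes fell. No interferon gene rose. Of 73 oxidative phosphorylation genes 33 fell and 40 did not pass, with 48 falling adjusted over the list alone (fry adjusted p = 0.00545, and adjusted p = 0.310 with an estimated correlation). Of 80 ribosomal protein genes 49 fell and 31 did not pass, with 61 falling adjusted over the list alone (fry adjusted p = 0.00106, and adjusted p = 0.192 with an estimated correlation). Of 28 genes of endoplasmic reticulum stress 10 fell, the chaperones Hspa5 (-0.41), Sdf2l1 (-0.57 ± 0.12, adjusted p = 0.00416) and Manf (-0.36) among them, and 18 did not pass; 15 fell adjusted over the list alone (fry adjusted p = 0.0310, and adjusted p = 0.423 with an estimated correlation). Of 29 interferon response genes 5 rose, including Oasl2 (0.42), Ifit1 (0.44) and Irf7 (0.39), and 24 did not pass; 9 rose adjusted over the list alone (fry adjusted p = 0.0310, and adjusted p = 0.423 with an estimated correlation). Of 10 blood genes 4 fell and 6 did not pass, with 8 falling adjusted over the list alone, a mean of -0.35 and the comparison's lowest fry adjusted p (0.00103, and adjusted p = 0.192 with an estimated correlation). Fry also called falls of cholesterol synthesis (adjusted p = 0.0211; 5 of 26 fell, 15 adjusted over the list alone), oligodendrocyte precursors (0.0385; 2 of 15 and 5) and immediate early genes (0.0429; 1 of 30 and 13), and a rise of the channels (0.0382; 1 of 44 and 9), each at adjusted p = 0.423 with an estimated correlation. Zbtb16 rose (0.54 ± 0.11, adjusted p = 0.00303), and Hbb-bs (-0.67) and Ccr1 (-0.66) fell.

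Genes called between HT and WT over all treatments were concentrated beside Shank2: 8 of 26 tested genes within 1 Mb (30.8%), against 569 of 15344 on other chromosomes (3.71%). Whether reads of Shank2 were given to genes that overlap it was not testable, since no tested neighbour overlaps Shank2 and so 0 could be called. An effect of the altered allele on genes within 1 Mb may account for the pattern, with a two-sided Fisher's exact p of 3.23e-06 and an odds ratio of 11.5. Flanking DNA of another strain, carried along with the allele, cannot be told apart from such an effect, and no sequence variants were analysed here. From 1 to 10 Mb 6 of 89 genes were called (6.74%, Fisher's exact p = 0.148, odds ratio 1.88). Among the 6 were Cfap46, Lrrc27 and Dpysl4, at 4318.1, 4758.9 and 4899.2 kb from Shank2. Neighbouring genes are not independent of each other, so these p-values are descriptive.

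Labels were redrawn within sex and the other factors (for sex differences, across sex), and each gene count was set against those of other splits. In several comparisons the real split gave the most genes, at 1 of 100 splits. The real count and the highest other were 55 and 3 for fluoxetine in HT, and 148 and 1 for lithium. In WT they were 140 and 2 for fluoxetine, and 1421 and 239 for lithium. For genotype they were 4 and 3 in females, and 668 and 521 in males. Within WT males they were 472 and 65 for fluoxetine, and 1698 and 1489 for lithium. Redrawing treats libraries as independent, and the labels give no litter, so chance differences between litters cannot be excluded. Without WT vehicle male 2 the counts were 5 for fluoxetine in WT and 3 for genotype in males. In WT males they were then 0 for fluoxetine and 133 for lithium. For genotype over both sexes 3 of 100 splits gave at least 127 genes; the highest other gave 737, several times the real count, which points to a structure of the samples whose source was not tested. For fluoxetine in WT females 4 of 100 splits gave at least 3 genes (highest other 27), and for lithium in HT females 7 of 100 gave at least 1 (highest other 75), so chance cannot be excluded for the latter, and here too other splits reached several times the real count. The margin was narrow for genotype in females, genotype in males and lithium in WT males. Where 0 genes were called every split gave as many: 100 of 100 for fluoxetine in HT females (highest other 1), fluoxetine in HT males (12), lithium in HT males (0), the sex differences in genotype (107), fluoxetine in HT (2), lithium in HT (16) and lithium in WT (196), and the genotype differences in fluoxetine (20) and lithium (1), and 35 of 35 for lithium in WT females (1). For lists called by camera, adjusted within an effect, the real labels gave 22 for genotype, and 4 of 100 splits gave as many (highest other 24). Chance cannot be excluded for the number of lists in fluoxetine in HT (17, 10 of 100 splits, highest other 23), lithium in HT (6, 89 of 100, highest other 23), fluoxetine in WT (16, 17 of 100, highest other 21) and lithium in WT (14, 38 of 100, highest other 21); other splits called a median of 10 to 13 lists.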
